A study of Homo sapiens with 15 samples.

How the data were processed

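RNA was measured in HepG2 cells, a human hepatocellular carcinoma line, after 72 h with tris(2-chloroethyl) phosphate (TCEP) at 25 or 250 µM, tris(2-chloroisopropyl) phosphate (TCIPP) at 2.5 or 25 µM, or the solvent dimethyl sulfoxide (DMSO) at 0.1%. Both compounds are chlorinated organophosphate flame retardants, and TCIPP carries a methyl group on each chloroalkyl arm that TCEP lacks. Each of the 5 groups had 3 libraries. Per the labels' protocols, the cultures of each triplicate were seeded, treated and extracted separately, and poly-A stranded libraries were sequenced on an Illumina HiSeq as paired-end reads of 50 bp. Which replicates shared a day, plate or sequencing lane is not given in the sources used here.

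The authors mapped and counted the reads with CLC Genomics Workbench, per the series' design text, and its version is not given in the sources used here. The human build was hg19 (GRCh37), per the submitters' processing notes. Per the file headers, each library's deposited table holds whole-number read counts per gene, namely total and unique gene reads, total and unique exon reads and intron reads. The deposited RPKM values, per the file headers, are reads per kilobase of exon scaled to the mapped reads, and recomputing them from the exon reads and exon lengths gave the deposited value in 100% of genes within a relative tolerance of 0.0001. The authors also deposited quantile-normalized expression values, a signal on a linear scale. These were normalized in 2 sets of 9 libraries, 1 for each compound with DMSO, and the DMSO files hold the values of the TCEP set. They were therefore used only for an alternative within the TCEP set. Whether the counting used the strand is not given in the sources used here, so reads of a gene and of an antisense partner cannot be separated.

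Each table listed 57773 genes. Of these, 20986 had an exon length of 0 and 0 of those had exon reads, so they were left out of the exon-read tests. A total of 27 gene names had been turned into dates and were restored from their Ensembl identifiers. Of the identifiers, 55538 (96.1%) matched the gene name table used here. Gene starts in the tables lie 1 base below the annotation for 35891 of 41552 genes with the same end (86.4%), so the starts given here were moved to a 1-based scale. Gene annotation entered only for names, GC content and this check.

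Total exon reads per library ran from 5.35 to 26.8 M (megareads) with a median of 8.89 M. A count of 3 reads corresponded to 0.112 to 0.560 CPM, counts scaled to a megaread, per library. The 95% confidence interval of a log2 fold change reached a median of 0.25 to 0.26 to either side over the comparisons. Reads carry no molecular identifiers, so floors cover counting error only. About 86% to 87% of exon reads were unique to 1 place in each library. For genes with a low unique share, reads may belong to near-identical copies. The share stands beside many such genes at 1 or more of their mentions. It is not repeated beside MT1X (57.2%), LOX (57.9%), DDIT3 (59.6%), FKBP9L (61.9%), LYZ (62%), WARS (63.9%), HMGCS1 (64%) and AKR1C1 (72.2%).

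The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on total exon reads, with TMM scaling, edgeR's own filter on low counts and all 15 libraries in 1 fit, which left 12567 genes. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. Levels are mean CPM ± SD over 3 libraries. There were 7 comparisons: each treatment against DMSO, the higher against the lower concentration of each compound, and TCIPP against TCEP at the concentration they share, 25 µM. The tests, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined.

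Named genes were picked by rule. Against DMSO these were up to 10 genes per direction, and in the other comparisons up to 5, with the largest change among called genes that had a mean of at least 1 CPM and no overlap between groups. Where fewer than 5 passed, the 5 genes with the smallest p were named as not passing. Up to 4 members with the smallest p were named for each gene list that passed or held called genes, and a fixed set of genes was always looked up, among them CYP1A1, CYP3A4, CYP2B6, HMOX1, NQO1, CDKN1A, ATF3, DDIT3, HMGCS1, CPT1A, CYP7A1, MT1X, MKI67 and ALB. Genes named outside this rule are said to be so, and some genes that the rule picked are not reported here.

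In all, 41 gene lists were written from textbook knowledge, covering xenobiotic metabolism, stress responses, the cell cycle, lipid and carbohydrate metabolism, liver functions and markers of other cell types. They hold 1263 genes, of which 1243 were matched, 949 were tested and 102 stand in more than 1 list. The 40 lists with at least 5 tested members were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, which compares a list with the other genes, and adjusted over the lists within each comparison. The same test with a correlation estimated per list was run beside it, as was fry, which tests whether the members move on balance in 1 direction. Counts of members adjusted over the list alone use the gene test's p-values. The markers of endothelial cells had too few tested members.

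The labels give each group replicates 1, 2 and 3. Whether equal numbers pair the libraries was checked from the correlation of deviations from the group means, before the calls of the fits were compared. In the 3 comparisons between treated groups every same-numbered pair correlated at over 0.1: 0.197 to 0.286 for the TCEP concentrations, 0.277 to 0.297 for the TCIPP concentrations and 0.177 to 0.272 for the compounds at 25 µM. Correlations between different numbers lay between -0.201 and 0.0212. The numbers were therefore taken to pair the treated libraries, and a fit with the replicate number as a block is given beside those comparisons. The pairing comes from the data and the shared numbers, and what the numbers stand for is not given in the sources used here.

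Alternatives were DESeq2 1.42.0, limma-voom, the relative log expression scaling, library totals, unique reads, total gene reads, no low-count filter, a filter of 5 CPM in 3 libraries, a fit of only the groups compared, an absolute log2 fold change of at least 1, reads thinned to the shallowest library, the deposited quantile-normalized values on the log2(value + 1) scale, and each library left out in turn. Comparisons that share the DMSO libraries were set against 100 simulations of unchanged groups. The fit was tested on simulated data with 50 genes changed at each size. Each run held changes of every size at once, which eases the adjusted cutoff for the 1.5-fold genes. Where few genes change, the fit may recover fewer of them. For TCEP at 250 µM against DMSO it recovered 68%, 78% and 100% of the 1.5-, 2- and 4-fold changes with 4.02% false calls. For TCIPP at 25 µM against DMSO these were 60%, 76% and 98% with 1.2%. The lower concentrations gave 62%, 90% and 94% with 6.01% for TCEP at 25 µM, and 62%, 86% and 92% with 3.45% for TCIPP at 2.5 µM. With the block, the TCEP concentrations gave 74%, 84% and 98%, with false calls of 11.9%, above the 5% aimed for. The TCIPP concentrations with the block gave 52%, 86% and 92% with 5.75% false calls, and the compounds at 25 µM gave 68%, 92% and 96% with 5.98%. Tables were handled with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15, and figures were drawn with matplotlib 3.10.9.

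The pair of libraries closest to each other had a chi-square of 2.31 per gene, above sampling noise, so no library was counted as a duplicate of another. Nothing was left out of the 15 libraries.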

Results

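HepG2 is a human liver cancer line that keeps many hepatocyte functions, such as secreting albumin and lipoproteins. Its RNA was compared after 72 h with TCEP at 25 or 250 µM, TCIPP at 2.5 or 25 µM, or 0.1% DMSO, with 3 libraries in each of the 5 groups. The series calls the concentrations of each compound low and high, so it asks what each exposure changed against the solvent, what the higher concentration added, and how the related compounds compared. Total exon reads in replicates 1, 2 and 3, in megareads (M), were 7.91, 8.02 and 21.4 M with DMSO, 10.5, 9.05 and 14.7 M with TCEP at 25 µM, and 7.36, 6.63 and 21.0 M with TCEP at 250 µM. With TCIPP they were 7.11, 6.78 and 26.8 M at 2.5 µM and 8.91, 5.35 and 8.89 M at 25 µM. Intron reads made up 8.90 ± 0.211% of gene reads with DMSO (SD, n = 3), 8.23 ± 0.306% and 8.50 ± 0.228% with TCEP at 25 and 250 µM, and 8.10 ± 0.490% and 8.998 ± 0.496% with TCIPP at 2.5 and 25 µM. Mitochondrial genes took 6.997 ± 0.709%, 6.15 ± 0.341%, 6.60 ± 0.163%, 6.04 ± 0.344% and 7.03 ± 0.293% of exon reads in the same order. The first principal component held 22.7% of the variance and the second 11.2%.

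At 250 µM TCEP, genes of the ATF4 amino acid response, which serve amino acid synthesis, amino acid import and tRNA charging, rose as a group against DMSO. Of its 31 tested members, 19 rose and 0 fell adjusted over the list alone, and 29 had a positive fold change, with a median log2 fold change of 0.26 (camera adjusted p = 3.84e-26). ASNS, asparagine synthetase (ENSG00000070669, hg19 chromosome 7, 97481430 to 97501854), stood at 142 ± 7.54 CPM against 100.2 ± 8.61 (SD, n = 3). Its log2 fold change was 0.50 ± 0.0764 (SE) with an adjusted p of 0.0624 over all genes. MTHFD2, a mitochondrial folate enzyme with 54.2% unique reads, stood at 334.8 ± 10.2 against 261 ± 6.25 CPM (log2 fold change 0.36, adjusted p = 0.0753). CTH, which makes cysteine from cystathionine, and GARS, the glycyl-tRNA synthetase, had log2 fold changes of 0.425 and 0.32 (adjusted p = 0.212 and 0.230). NPIPP1, a pseudogene with 6.34% unique reads, completes the 5 genes with the smallest p (0.81, adjusted p = 0.0753).

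The ATF4 list also passed with an estimated correlation (adjusted p = 0.00742). With the replicate block 0 lists did so, though the numbers were not taken to pair libraries with DMSO. A further 7 lists passed camera at 250 µM TCEP, and none of those did with an estimated correlation (adjusted p = 0.625 to 0.752 with an estimated correlation). The unfolded protein response (adjusted p = 0.00368) and the cytosolic ribosomal proteins (9.07e-05, 69 of 79 with a positive fold change) were higher. Heat shock genes were lower (0.00297), with 3 of 21 falling adjusted over the list alone. Among these, the chaperone HSPH1 stood at 173.3 ± 17.4 against 228.6 ± 30.3 CPM and HSP90AA1 at 1312 ± 81.6 against 1574 ± 63.5 CPM (adjusted p over all genes 0.631 and 0.809). Genes of MHC class I and II (0.0365), liver cancer and progenitor genes (0.0462), immediate early genes (0.0299) and mitochondrially encoded genes (0.0210) were lower too. CD74, the MHC class II chaperone, fell adjusted over the list alone (47.8 ± 1.9 against 59.4 ± 1.45 CPM, adjusted p over all genes 0.424), as did CREB3L3 of the unfolded protein response list, a liver transcription factor (log2 fold change -0.51, 0.304). In 11 of 13 mitochondrially encoded genes the fold change was negative, and mitochondrial genes took 6.60% of reads here and 6.997% with DMSO. Leaving out any of the 6 libraries ended the call of 1 or more of these 7 lists (adjusted p 0.0513 to 0.578), while the ATF4 list passed each time. These fits used the preset correlation only, so its call with an estimated correlation was not tested with a library left out. Over single genes, edgeR called 0 of 12567 genes (653 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 17, and edgeR called 1 without DMSO replicate 2. The groups did not overlap in 1369 genes (10.9%), where chance gives 10%. With the replicate block, not taken to pair libraries with DMSO, edgeR called 34 genes.

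At 25 µM TCEP, hypoxia response and ribosomal protein genes were higher than in DMSO as groups, and NRF2 targets, which serve antioxidant defence, were lower. These calls were made at the preset correlation and were lost with an estimated one (adjusted p = 0.498, 0.498 and 0.436 with an estimated correlation). Of 30 hypoxia genes, 9 rose and 0 fell adjusted over the list alone (median log2 fold change 0.26, camera adjusted p = 7.99e-09). They include LOX, which crosslinks collagen (209.1 ± 37.6 against 140 ± 4.45 CPM), BNIP3 (log2 fold change 0.36) and ERO1L, an endoplasmic reticulum oxidase (0.60). Of 35 NRF2 targets, 14 fell and 1 rose adjusted over the list alone (median -0.16, 3.91e-06). The aldo-keto reductases AKR1B10 and AKR1C2 (62% unique reads) stood at 286 ± 36.2 against 464.2 ± 97.3 CPM and 417.9 ± 90.4 against 769.3 ± 141 CPM. HMOX1, heme oxygenase, was the member that rose (42.7 ± 3.78 against 31.9 ± 2.34 CPM). GPX2, a glutathione peroxidase with 11.7% unique reads, had a log2 fold change of -0.88. Over all genes these members had adjusted p of 0.116 to 0.143.

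Glycolysis genes (camera adjusted p = 0.00214) and S phase genes (0.00251, 42 of 48 with a positive fold change) were higher at 25 µM TCEP too. None of the 9 lists that passed there did so with an estimated correlation (adjusted p = 0.436 to 0.555 with an estimated correlation). In glycolysis 5 of 29 rose adjusted over the list alone, among them PGK1 (1346 ± 144 against 1070 ± 35.2 CPM) and the glucose transporter SLC2A3 (1195 ± 193 against 757.9 ± 92.5 CPM). Ribosomal protein genes had 8 of 79 rise adjusted over the list alone (5.25e-14), among them RPL34 (416 ± 25.1 against 348 ± 25.4 CPM). Cholesterol synthesis genes (0.000452, 2 of 27 fell, among them FDPS, farnesyl diphosphate synthase, at log2 fold change -0.245), heat shock genes (0.0495, 3 of 21 fell) and immediate early genes (0.0144, 3 of 23 fell and 1 rose) were lower. So were the 13 mitochondrially encoded genes (2.48e-05), all with negative fold changes and 3 of which fell adjusted over the list alone, where mitochondrial reads were 6.15% against 6.997% and intron reads 8.23% against 8.90%.

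Over single genes at 25 µM TCEP, edgeR called 0 genes (1915 at an unadjusted p under 0.05), limma-voom 4 and DESeq2 155. The genes with the smallest p were MATN3, a matrix protein (591.2 ± 34.6 against 405.9 ± 55.5 CPM, 66.1% unique reads), FHL2, a LIM domain cofactor (94.0 ± 7.1 against 56.2 ± 6.16 CPM), and EGR1, an immediate early transcription factor (ENSG00000120738, chromosome 5, 137801179 to 137805004; 12.8 ± 1.52 against 24.8 ± 4.97 CPM). Their log2 fold changes of 0.54 ± 0.0852, 0.74 ± 0.121 and -0.92 ± 0.151 each had an adjusted p of 0.0529. VCAN, the proteoglycan versican (0.725, 31.8% unique reads, 0.0762), and CTD-2616J11.11 (-2.88, 7.88% unique reads, 0.0874) followed. No overlap between the groups was seen in 2857 genes (22.7%, chance 10%). Without DMSO replicate 2 the count was 29, without DMSO replicate 3 it was 2, and leaving out any library but TCEP 25 µM replicate 2 ended the call of the heat shock or immediate early list (adjusted p 0.0780 to 0.205). With the replicate block edgeR called 1037 genes, though the numbers were not taken to pair libraries with DMSO. The count of 0 thus depends on that choice.

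At 25 µM TCIPP, YARS, the tyrosyl-tRNA synthetase, rose against DMSO (ENSG00000134684, chromosome 1, 33240840 to 33283754). It stood at 162.9 ± 9.56 against 116.6 ± 6.66 CPM (SD, n = 3), a log2 fold change of 0.485 ± 0.0713 (SE; adjusted p = 0.0411) and higher in 3 of 3 libraries. It belongs to the ATF4 amino acid response, of which 23 of 31 members rose and 0 fell adjusted over the list alone (median log2 fold change 0.29, camera adjusted p = 4.92e-28, and adjusted p = 0.00562 with an estimated correlation). CTH was at 31.9 ± 0.768 against 22.8 ± 1.32 CPM, MTHFD2 at 334.2 ± 11.4 against 261 ± 6.25 and TRIB3, a pseudokinase of this response, at 211.1 ± 12 against 156.7 ± 17.6 (adjusted p over all genes 0.0538, 0.0538 and 0.0830). ASNS had a log2 fold change of 0.40 ± 0.077 (0.0969). The plot of the ATF4 list's mean per library shows both higher concentrations above DMSO.

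**Figure D1:**
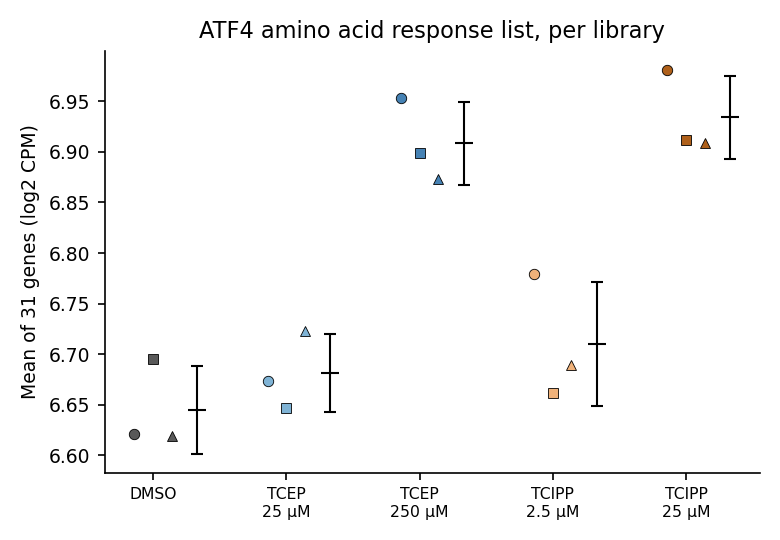
Mean log2 CPM of the 31 ATF4-list genes in each library, by group, with the group mean ± SD as a bar and circle, square and triangle for replicates 1, 2 and 3. The means were 6.64 ± 0.0436 with DMSO, 6.68 ± 0.0387 and 6.91 ± 0.0409 with TCEP at 25 and 250 µM, and 6.71 ± 0.0613 and 6.93 ± 0.0405 with TCIPP at 2.5 and 25 µM.

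Besides ATF4, 8 lists passed camera at 25 µM TCIPP, and none of them did with an estimated correlation (adjusted p = 0.162 to 0.676 with an estimated correlation, and 0.162 for heat shock genes). Of 21 heat shock genes, 4 fell adjusted over the list alone (camera adjusted p = 2.30e-05), among them HSP90AA1 (1122 ± 148 against 1574 ± 63.5 CPM, adjusted p over all genes 0.0538) and CHORDC1, an HSP90 cochaperone (log2 fold change -0.395, 0.240). In the unfolded protein response 2 of 29 rose (3.10e-05), ERN1, its kinase sensor (0.52 ± 0.108, 0.139), and HERPUD1 (198.6 ± 13.2 against 156.6 ± 22.0 CPM, 0.238). The hypoxia list was higher (0.0206), with 1 of 30 rising, DDIT4, an inhibitor of mTOR (0.38, 23.6% unique reads). Phase II conjugation enzymes (0.0117, 25 of 31 negative), G2/M genes (0.00702, 43 of 52 negative), nuclear-encoded OXPHOS genes (0.00114, 62 of 75 negative), MHC genes (0.0206) and fibroblast and stellate markers (0.0206) were lower. The last list had 5 tested members, of which the smooth muscle genes TAGLN (13.1 ± 1.51 against 18.6 ± 1.02 CPM, adjusted p over all genes 0.224) and ACTA2 (-0.34, 0.575) fell adjusted over the list alone. GSTA2, a glutathione transferase, had a log2 fold change of -0.77 ± 0.293 and the kinesin KIF20B -0.51 ± 0.193 (both 0.661).

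YARS was the 1 gene that edgeR called at 25 µM TCIPP (799 at an unadjusted p under 0.05). The same count was 1 with limma-voom and 34 with DESeq2. ACOT13, a thioesterase, had a small p without passing (29.1 ± 0.54 against 39.1 ± 0.518 CPM, adjusted p = 0.0538). YARS was not called without TCIPP 25 µM replicate 1 (0.104) or 2 (0.111), DMSO replicate 1 (0.136) or 3 (0.253), with library totals (just above 0.05) or with only the groups compared (0.625), and without DMSO replicate 2 the count was 5. Each of the 6 libraries, left out, ended the call of 1 or more of the 8 lists (adjusted p 0.0534 to 0.974), and the ATF4 list passed each time. These fits, too, used the preset correlation only. The groups did not overlap in 1141 genes (9.08%, chance 10%). With the replicate block, not taken to pair libraries with DMSO, edgeR called 47 genes.

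At 2.5 µM TCIPP, 12 genes changed against DMSO, 9 up and 3 down. FHL2 (ENSG00000115641, chromosome 2, 105974169 to 106054970) was at 93.0 ± 9.92 against 56.2 ± 6.16 CPM (SD, n = 3; log2 fold change 0.72 ± 0.121 SE), and DUSP1, a MAP kinase phosphatase with 21.4% unique reads, at 117.6 ± 4.08 against 71.2 ± 10.0 CPM (0.73 ± 0.116). MATN3 (ENSG00000132031, chromosome 2, 20191872 to 20212455) was at 576.5 ± 23.5 against 405.9 ± 55.5 CPM (0.51 ± 0.0853). ETNPPL, which breaks down phosphoethanolamine (ENSG00000164089, chromosome 4, 109663196 to 109684210), fell to 1.17 ± 0.28 from 5.39 ± 2.17 CPM (-2.17 ± 0.361). SPP1, the secreted phosphoprotein osteopontin (ENSG00000118785, chromosome 4, 88896819 to 88904562), fell to 877.5 ± 123 from 1462 ± 216 CPM (-0.74 ± 0.136), and CHORDC1 to 49.6 ± 4.66 from 72.3 ± 1.7 CPM (-0.53 ± 0.0939). The other genes that rose were BEAN1 (1.48 ± 0.266, 33.2% unique reads), QSOX1, which forms disulfide bonds in secreted proteins (0.625 ± 0.112), ZNF395 (0.54 ± 0.0832, 64.2% unique reads), BPIFB2 (0.49 ± 0.0813), TMEM45B (0.445 ± 0.0789) and RAPGEF1, a guanine nucleotide exchange factor (0.43 ± 0.0723). Adjusted p-values were 0.0312 to 0.0488, with no overlap between the 3 treated and 3 DMSO libraries.

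The hypoxia response held the most members that moved at 2.5 µM TCIPP: 18 of 30 rose and 0 fell adjusted over the list alone (median log2 fold change 0.34, camera adjusted p = 2.45e-13). That call was lost with an estimated correlation, as were all 11 list calls at this concentration (adjusted p = 0.281 for hypoxia and 0.281 to 0.521 over the lists with an estimated correlation). CA9, carbonic anhydrase IX, stood at 87.0 ± 9.41 against 57.0 ± 9.7 CPM, and LOX had a log2 fold change of 0.68 ± 0.145 (both adjusted p = 0.0571 over all genes). In glycolysis 13 of 29 rose (6.99e-09), among them GAPDH (5170.0 ± 495 against 3766 ± 422 CPM, 78.7% unique reads) and SLC2A3 (0.76 ± 0.181). Lipid droplet and lipoprotein genes were higher (0.0271, 5 of 32 rose), with the HDL receptor SCARB1 at 0.45 ± 0.0961, as were ribosomal proteins (1.44e-08) and the ATF4 list (0.0164, 0 of 31 rose). NRF2 targets were lower (0.000255): 9 of 35 fell, including AKR1B10 (-0.64 ± 0.18) and AKR1C2 (-0.86 ± 0.237), and HMOX1 rose adjusted over the list alone (46.3 ± 7.98 against 31.9 ± 2.34 CPM). Steroid hormone metabolism genes (0.0375, 5 of 26 fell and 1 rose), where AKR1C1 stood at 1093 ± 402 against 2134 ± 426 CPM, heat shock genes (0.000663, 5 of 21 fell), cholesterol synthesis genes (0.00153, 1 of 27 fell) and G2/M genes (0.000237, 45 of 52 negative) were lower. All 13 mitochondrially encoded genes had negative fold changes and 5 fell (5.78e-07), among them MT-ATP8 (980.3 ± 52.7 against 1240 ± 108 CPM), where mitochondrial reads were 6.04% against 6.997% and intron reads 8.10% against 8.90%.

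For TCIPP at 2.5 µM, edgeR's count of 12 (1743 at an unadjusted p under 0.05) compares with 104 by limma-voom and 232 by DESeq2. It was 117 without TCIPP 2.5 µM replicate 1, 307 without DMSO replicate 2 and 0 without TCIPP 2.5 µM replicate 2 or 3 or DMSO replicate 1 or 3, and 0 with total gene reads, where the 12 genes had adjusted p of 0.0604 to 0.0719. The ATF4 call was lost without TCIPP 2.5 µM replicate 1 (0.320) or DMSO replicate 3 (0.0976). The G2/M, lipid droplet or steroid calls were lost without TCIPP 2.5 µM replicate 1, 2 or 3 or DMSO replicate 1 or 3 (0.0502 to 0.135). No overlap between the groups was seen in 2107 genes (16.8%, chance 10%). With the replicate block edgeR called 941 genes, though the numbers were not taken to pair libraries with DMSO. The count of 12 thus depends on that choice.

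**Figure D2:**
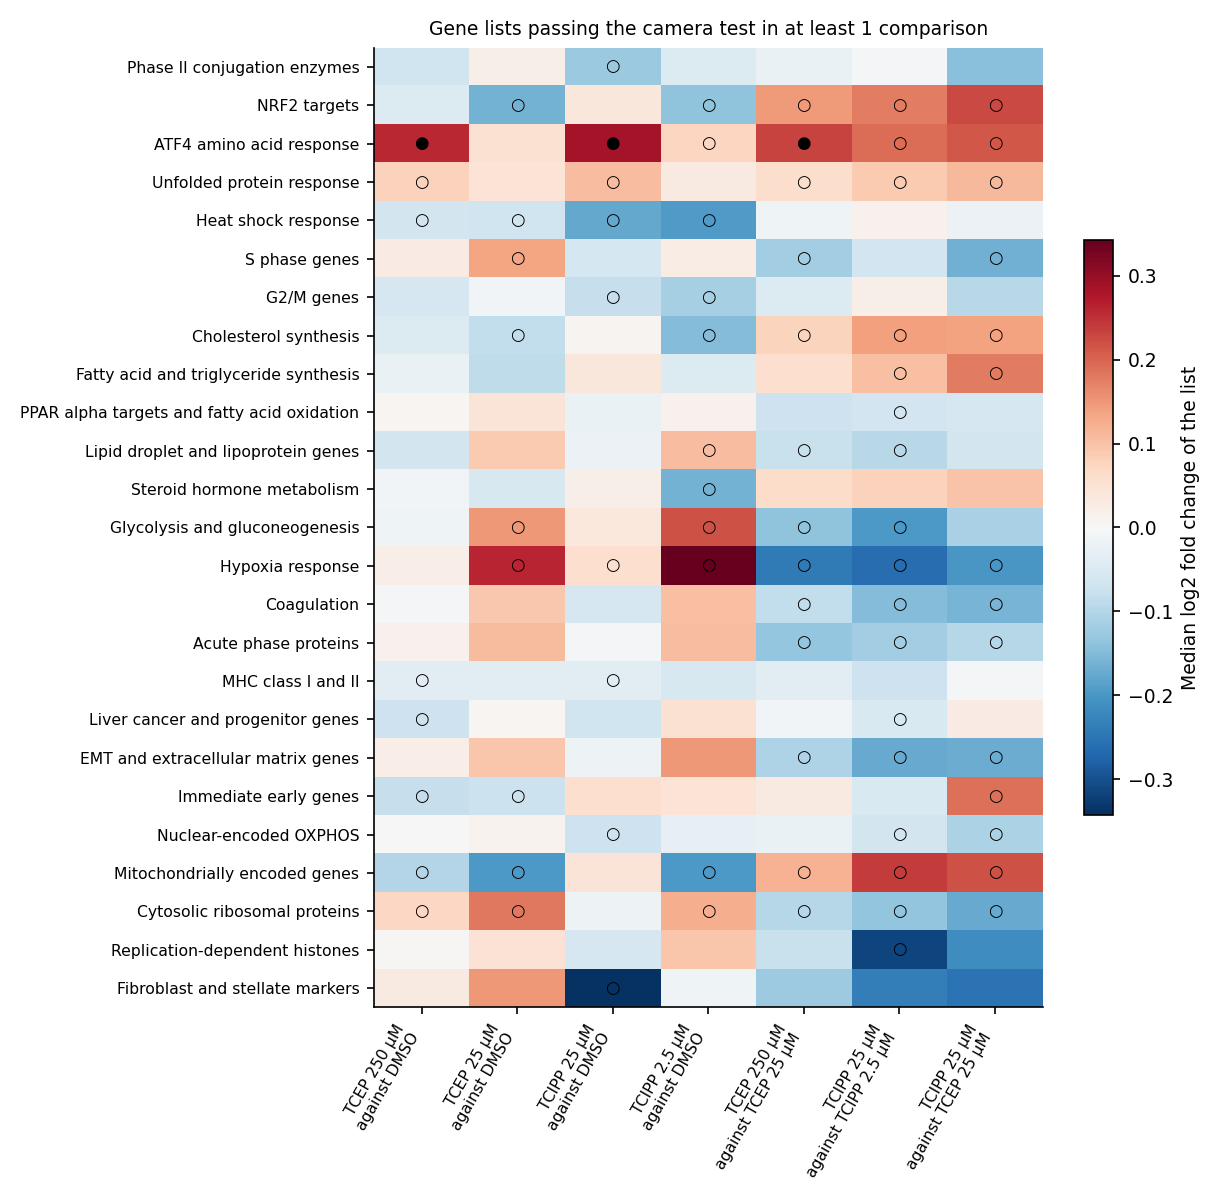
Median log2 fold change of the 25 gene lists that passed camera in 1 or more of the 7 comparisons, one column per comparison; an open circle marks an adjusted p under 0.05 at the preset correlation and a filled circle one that also held with an estimated correlation. The ATF4 list was higher at both higher concentrations (medians 0.26 and 0.29), and the hypoxia list, at the preset correlation, at both lower ones (0.26 and 0.34).

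Fold changes against DMSO were compared across the 12567 genes, which are not independent replicates, between treatments that share the DMSO libraries. The lower concentrations, TCEP at 25 µM and TCIPP at 2.5 µM, correlated at 0.719, where unchanged groups against the same controls gave 0.499 (0.451 to 0.542 in 100 simulations), with a covariance of 0.0518 against 0.0208. The higher concentrations correlated at 0.490 against a simulated 0.471 (0.439 to 0.495), with a covariance of 0.0228 against 0.0208, and the correlation ran from 0.375 without TCIPP 25 µM replicate 2 to 0.625 without DMSO replicate 2. TCEP and TCIPP, both at 25 µM, correlated at 0.315 against 0.474 (0.444 to 0.505), with a covariance of 0.0190 against 0.0208. Within TCEP the concentrations correlated at 0.593 against 0.496 (covariance 0.0338 against 0.0209), and within TCIPP at 0.426 against 0.474 (0.0251 against 0.0208). The 3 DMSO libraries cannot be split into parts of at least 2, so part of any excess may come from the shared controls. The simulated libraries were independent, so an effect that same-numbered treated libraries share and the DMSO libraries do not is missing from the simulated values and may be another part of an excess. The simulated genes were independent too, so genes that vary together may widen the ranges beyond those given.

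From 25 to 250 µM TCEP, ATF4 genes rose as a group. In the ATF4 list 15 of 31 rose adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 3.83e-16, and adjusted p = 0.0448 with an estimated correlation). With the replicate block 9 of them passed over all genes, among them GARS (0.30 ± 0.0484, 0.00588) and WARS, the tryptophanyl-tRNA synthetase (0.405 ± 0.0812, 0.0188), while the blocked list had an adjusted p of 0.0897 with an estimated correlation. Of 30 hypoxia genes, 8 fell adjusted over the list alone (median -0.24, camera adjusted p = 2.22e-11, but adjusted p = 0.280 with an estimated correlation). With the block 11 of them passed over all genes, including EGLN3, a prolyl hydroxylase that marks HIF for degradation (46.1 ± 7.31 against 67.5 ± 9.91 CPM, blocked log2 fold change -0.54 ± 0.073, adjusted p = 0.00208; ENSG00000129521, chromosome 14, 34393437 to 34931980), and CA9 (-0.51 ± 0.0772). IGFBP3, which binds insulin-like growth factors (ENSG00000146674, chromosome 7, 45951949 to 45961473), stood at 57.1 ± 22.7 against 120.9 ± 47.3 CPM, with -1.09 ± 0.374 unblocked (adjusted p = 0.622) and -1.07 ± 0.0814 blocked (4.29e-06). NR1H4, the bile acid receptor FXR (ENSG00000012504, chromosome 12, 100867486 to 100958191), stood at 51.4 ± 8.28 against 34.1 ± 5.4 CPM (blocked 0.58 ± 0.0766, 0.00208). Against DMSO the hypoxia list at 250 µM TCEP had a median log2 fold change of 0.0218 (camera adjusted p = 0.940). EGLN3 and IGFBP3 lay nearer to their DMSO levels at 250 µM than at 25 µM TCEP.

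Among other lists from 25 to 250 µM TCEP, NRF2 targets were higher (camera adjusted p = 4.44e-06), with 5 genes up and 1 down over all genes with the block, AKR1B10 (0.42 ± 0.067) and AKR1C1 (0.60 ± 0.107) up and HMOX1 (-0.37 ± 0.0823) down. Neither this list nor any below passed with an estimated correlation (adjusted p = 0.106 to 0.519 with an estimated correlation, and 0.0897 to 0.551 blocked). The unfolded protein response (0.0106), cholesterol synthesis (0.00324) and mitochondrially encoded genes (0.00779) were higher too, the last with mitochondrial reads of 6.60% against 6.15%. Glycolysis (2.12e-05), ribosomal proteins (7.09e-08), S phase (0.00324), lipid droplet and lipoprotein genes (0.00324), coagulation (0.00901), EMT and extracellular matrix genes (0.0297) and acute phase proteins (0.0393) were lower. Complement genes were lower only with the block (0.0260). In glycolysis 2 fell adjusted over the list alone, and with the block PGK1 (-0.34), SLC2A3 (-0.46) and 3 others passed over all genes.

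Over single genes from 25 to 250 µM TCEP, edgeR called 0 (900 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 14. With the block edgeR called 185, 67 up and 118 down (1650 at an unadjusted p under 0.05), limma-voom 156 and DESeq2 220. The unblocked fit's smallest adjusted p was 0.458, shared by PPFIA4 (-1.045, blocked 0.0188), FMO5 (-0.33, 50.2% unique reads, blocked 0.0123), VCAN (-0.61, blocked 0.00334), GTF2H2 (0.52, 14.7% unique reads, blocked 0.0117) and MATN3 (-0.41, blocked 0.00464). The largest blocked rises were HOXD1 (0.96 ± 0.14), FCGBP (0.78 ± 0.122), SLC6A9 (0.75), SLC2A6 (0.73) and SLC6A14 (0.68), and the largest falls besides IGFBP3 and PPFIA4 were MSH5-SAPCD1 (-1.70, 2.56% unique reads), FAM69C (-1.29) and LOXL3 (-1.05 ± 0.155). The blocked count was 18, 22 or 70 without TCEP 250 µM replicate 1, 2 or 3 and 27, 37 or 111 without TCEP 25 µM replicate 1, 2 or 3, and 555 in a fit of the 12 treated libraries. Leaving out TCEP 250 µM replicate 1, 2 or 3 or TCEP 25 µM replicate 1 or 2 ended the call of the unfolded protein response, S phase, lipid droplet, coagulation, acute phase, EMT or mitochondrial list (adjusted p 0.0505 to 0.227). The groups did not overlap in 1879 genes (14.95%, chance 10%).

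From 2.5 to 25 µM TCIPP, hypoxia and glycolysis genes fell as groups, and ATF4 and mitochondrially encoded genes rose. All of these calls were made at the preset correlation and were lost with an estimated one (adjusted p = 0.183, 0.150, 0.0954 and 0.150 with an estimated correlation). In the hypoxia list 7 of 30 fell adjusted over the list alone (median log2 fold change -0.26, camera adjusted p = 2.38e-08) and 14 passed over all genes with the block, among them EGLN3 (46.0 ± 7.79 against 75.0 ± 14.3 CPM, blocked -0.705 ± 0.0752, adjusted p = 0.000114). In glycolysis 8 of 29 fell and 1 rose (3.81e-07), with PGK1 at -0.31 blocked (0.00600). In the ATF4 list 14 of 31 rose and all 31 had a positive fold change (1.03e-12), with GARS at 0.30 ± 0.0489 blocked (0.00274). Of 13 mitochondrially encoded genes, 9 rose adjusted over the list alone (1.71e-09), among them MT-ATP8 (1310 ± 69.5 against 980.3 ± 52.7 CPM), and mitochondrial reads were 7.03% against 6.04% and intron reads 8.998% against 8.10%. Of the NRF2 targets 8 of 35 rose and 1 fell (7.18e-07, but adjusted p = 0.150 with an estimated correlation), with AKR1B10 (0.55) and GCLM, a subunit of the enzyme that starts glutathione synthesis (0.48 ± 0.0837), up and HMOX1 (-0.57 ± 0.0857) down with the block. Against DMSO the hypoxia list was higher at both TCIPP concentrations at the preset correlation, so its fall here did not bring it below DMSO.

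Further lists were higher at 25 than at 2.5 µM TCIPP: the unfolded protein response (camera adjusted p = 0.000333), cholesterol synthesis (7.02e-05, 2 of 27 rose) and fatty acid and triglyceride synthesis (0.00935, 1 of 28 rose, GPAM, which starts glycerolipid synthesis, at 0.50 ± 0.0638 blocked). None of the lists that passed in this comparison did so with an estimated correlation (adjusted p = 0.0954 to 0.416 with an estimated correlation, and 0.0677 to 0.475 blocked). By fry, 13 of the 40 lists passed, and 24 with the block. Lower were ribosomal proteins (2.35e-11, 79 of 79 negative), EMT and extracellular matrix genes (0.000552, 2 fell), nuclear-encoded OXPHOS (0.00516), coagulation (0.00641), replication-dependent histones (0.0152, 0 of 13 fell), lipid droplet and lipoprotein genes (0.0218), PPAR alpha targets (0.0403), acute phase proteins (0.0403) and liver cancer and progenitor genes (0.0492, 4 fell, lost with the block at 0.0598). Steroid hormone metabolism (up, 0.0136) and complement (down, 0.0342) passed with the block.

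Over single genes from 2.5 to 25 µM TCIPP, edgeR called 0 (1358 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 72, and with the block 484, 194 up and 290 down (2061 at an unadjusted p under 0.05), limma-voom 465 and DESeq2 425. MATN3 had the smallest p (390.3 ± 9.67 against 576.5 ± 23.5 CPM, -0.56 ± 0.0857, adjusted p = 0.0625, blocked 0.000145). EDN1, the vasoconstrictor endothelin 1 (19.5 ± 2.33 against 31.1 ± 2.92 CPM), CTH (0.46) and XPOT, the tRNA export factor (297.1 ± 12.7 against 227.7 ± 19.3 CPM), each had 0.123 (blocked 0.000117, 0.00352 and 0.000531), and ACY1 (-0.39, 8.42% unique reads) 0.191. The largest blocked rises were GLP2R (3.23 ± 0.531), SLC6A12 (2.21 ± 0.392), ZNF320 (1.66), MSANTD3-TMEFF1 (1.32, 0% unique reads) and ASB3 (1.30, 0.707% unique reads). GLP2R lay at 1.64 ± 1.55 CPM and SLC6A12 at 24.3 ± 25.2 CPM, so their libraries spread as widely as their means. The largest falls were CETP, which transfers cholesteryl esters (-1.54 ± 0.377), FKBP9L (-1.49), EHD2 (-1.44), SLC16A6 (-1.44, 30.9% unique reads) and CTSS (-1.42). The blocked count was 228, 259 or 268 without TCIPP 25 µM replicate 1, 2 or 3 and 317, 176 or 135 without TCIPP 2.5 µM replicate 1, 2 or 3, and 948 in a fit of the 12 treated libraries. Leaving out TCIPP 25 µM replicate 2 or 3 or TCIPP 2.5 µM replicate 1, 2 or 3 ended the call of the PPAR alpha, lipid droplet, coagulation, acute phase, liver cancer, OXPHOS or histone list (adjusted p 0.0519 to 0.325). No overlap between the groups was seen in 1560 genes (12.4%, chance 10%).

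**Figure D3:**
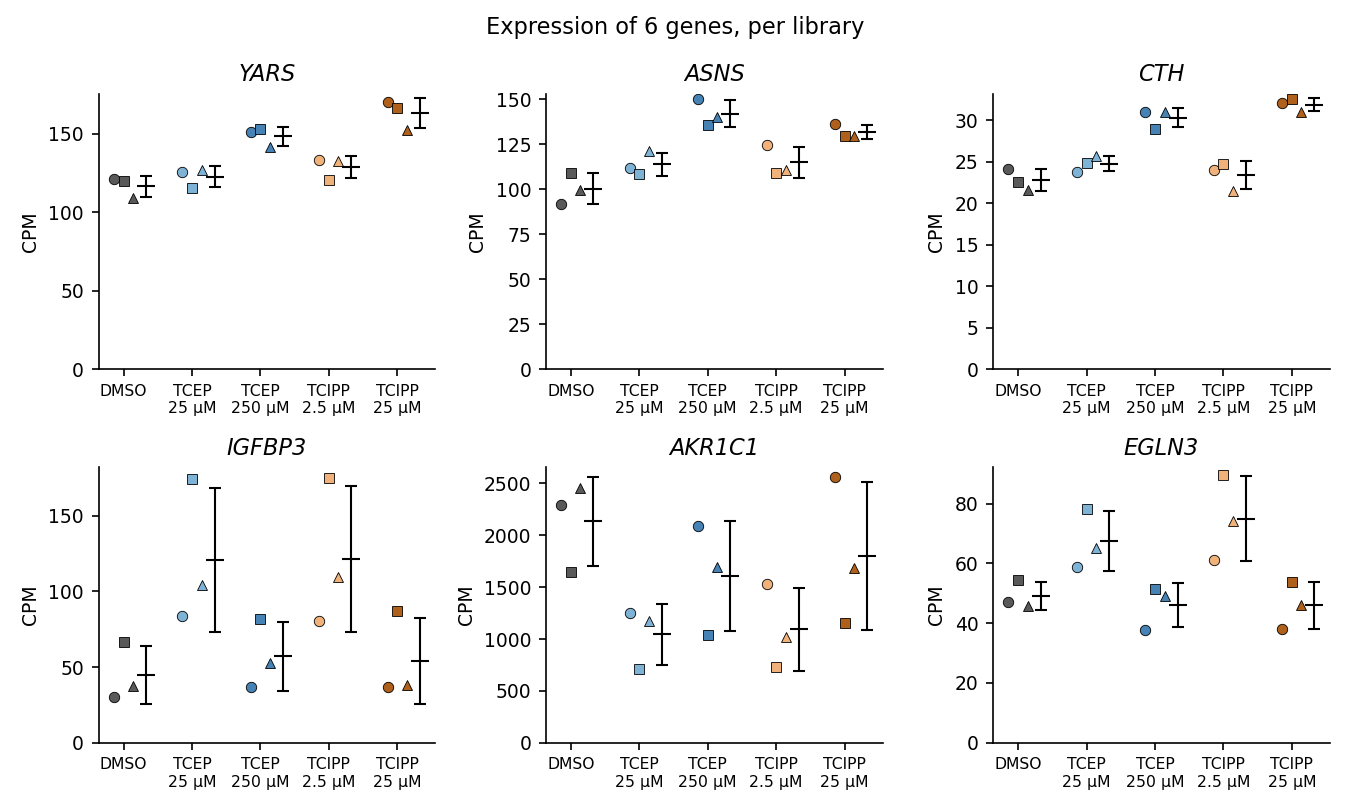
CPM in each library of YARS, ASNS, CTH, IGFBP3, AKR1C1 and EGLN3, genes picked for display after their values were seen, by group, with the mean ± SD and circle, square and triangle for replicates 1, 2 and 3. YARS averaged 162.9 CPM with TCIPP at 25 µM and 116.6 with DMSO, and EGLN3 46.1 and 46.0 at the higher against 67.5 and 75.0 at the lower concentrations of TCEP and TCIPP.

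The steps from the lower to the higher concentration share no libraries between the compounds. Across genes their log2 fold changes correlated at 0.404 (blocked 0.394, and 0.567 over genes of at least 5 CPM), with a covariance of 0.0238. Simulated unchanged groups gave -0.0420 to 0.0483. The simulated genes were drawn independently of each other, so genes that vary together may give unchanged groups a wider range than this. The correlation was 0.258 to 0.410 when 1 library was left out. A test of the difference between the steps called 0 genes (208 at an unadjusted p under 0.05, smallest adjusted p 1), and 0 with the block (408, 0.299), so no gene was shown to step differently with TCEP than with TCIPP. The concentrations differ between the compounds, 25 to 250 µM for TCEP and 2.5 to 25 µM for TCIPP.

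**Figure D4:**
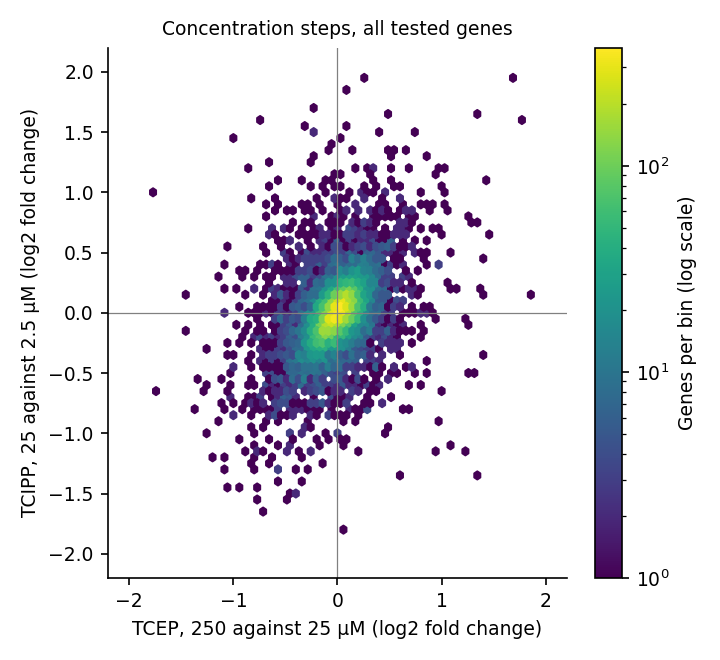
Log2 fold change of 12567 genes from 25 to 250 µM TCEP (x axis) against that from 2.5 to 25 µM TCIPP (y axis), with lighter hexagons for more genes, on a log scale. Both axes run from -2 to 2 and 3 genes lie outside. The cloud leans along the diagonal, with a correlation of 0.404 across genes.

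At the concentration that both compounds share, 25 µM, TCIPP differed from TCEP in 5 genes (n = 3 per group). The series calls this concentration high for TCIPP and low for TCEP, so a difference may also follow what sets high and low groups apart. Between the compounds at the levels called high, and at those called low, edgeR called 0 genes, with or without the block. AFF1, a transcription elongation factor (ENSG00000172493, chromosome 4, 87856154 to 88062206), was higher with TCIPP at 95.3 ± 8.29 against 69.9 ± 2.1 CPM, a log2 difference of 0.45 (95% interval 0.30 to 0.605, adjusted p = 0.0419). CYB5A, cytochrome b5 (ENSG00000166347, chromosome 18, 71920530 to 71959251), was at 90.4 ± 6.97 against 68.3 ± 1.35 CPM (0.41, 0.26 to 0.55, 0.0462). MATN3 was lower at 390.3 ± 9.67 against 591.2 ± 34.6 CPM (-0.60, -0.78 to -0.42, 0.0283). EDN1 (ENSG00000078401, chromosome 6, 12290596 to 12297427) was at 19.5 ± 2.33 against 31.3 ± 2.91 CPM (-0.69, -0.94 to -0.44, 0.0462), and VCAN (ENSG00000038427, chromosome 5, 82767284 to 82878122; 31.8% unique reads) at 16.3 ± 3.02 against 28.5 ± 1.63 CPM (-0.82, -1.10 to -0.54, 0.0419). With the block these genes had adjusted p of 9.17e-05 to 0.00141.

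ATF4 genes were higher with TCIPP than with TCEP at 25 µM, 16 of 31 adjusted over the list alone and all 31 with a positive difference (camera adjusted p = 4.90e-12), with TRIB3 at 0.44 ± 0.0741 blocked. The call was lost with an estimated correlation, as were those of all lists in this comparison (adjusted p = 0.0642 for ATF4 and 0.0642 to 0.370 over the lists with an estimated correlation, and 0.0912 to 0.373 blocked). NRF2 targets were higher (6.41e-07, 16 of 35 up and 1 down), led by AKR1B10 (438.6 ± 102 against 286 ± 36.2 CPM, blocked 0.60 ± 0.0673, 9.17e-05). Higher too were cholesterol synthesis (0.000278, 5 of 27 up), with MVK, mevalonate kinase, at 0.41 blocked (adjusted p = 0.0132), fatty acid and triglyceride synthesis (0.00192, 6 of 28 up and 1 down), the unfolded protein response (0.00159, 5 up and 1 down), immediate early genes (0.00159, 5 of 23 up), with FOS at 0.80 ± 0.171 and EGR1 at 0.64 ± 0.151 blocked, and mitochondrially encoded genes (6.22e-06, 8 of 13 up). Mitochondrial reads were 7.03% against 6.15% and intron reads 8.998% against 8.23%. Ribosomal proteins were lower (1.86e-13, 26 of 79 down), as were S phase genes (0.000112, 42 of 48 negative), hypoxia genes (0.00118), OXPHOS (0.00159), coagulation (0.00382, 4 down and 1 up), with the fibrinogen chain FGG at 787.8 ± 104 against 1069 ± 50.4 CPM, EMT genes (0.0172) and acute phase proteins (0.0457). NR1H4 stood at 54.7 ± 8.0 against 34.1 ± 5.4 CPM (blocked 0.68 ± 0.078, 0.000114), and glycolysis was lower only with the block (0.0149). All these differences, too, set a level called high against one called low.

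For most genes the compounds were not shown to differ at 25 µM, and the median 95% interval reached 0.26 log2 units to either side of the estimate. CYP1A1, the dioxin-responsive cytochrome P450, differed by 0.90 (0.04 to 1.77, adjusted p = 0.256), NQO1, a quinone reductase, by 0.15 (-0.03 to 0.33, 0.362) and ALB, albumin, by 0.07 (-0.22 to 0.36, 0.826). edgeR's count of 5 (2278 at an unadjusted p under 0.05) was 4 with limma-voom and 334 with DESeq2, and with the block 1100, 539 up and 561 down (3185 at an unadjusted p under 0.05). The largest blocked differences were SLC6A12 (2.585), GLP2R (2.36), RP11-762I7.5 (2.12, 4.44% unique reads), UCA1 (1.955, 28.8%) and RP4-798P15.3 (1.56, 4.05%) above, and TSPAN15 (-1.74), SLC16A6 (-1.66, 30.9%), MSH5-SAPCD1 (-1.63, 2.56%), CTSS (-1.575) and COL1A1 (-1.55) below. Without TCIPP 25 µM replicate 2 the unblocked count was 208 and without any of the other 5 libraries it was 0, as it was with only the groups compared. The blocked count was 293, 417 or 855 without TCEP 25 µM replicate 1, 2 or 3 and 313, 863 or 844 without TCIPP 25 µM replicate 1, 2 or 3, and 2096 in a fit of the 12 treated libraries. The hypoxia, coagulation, acute phase or OXPHOS call was lost without TCEP 25 µM replicate 1 or 2 or TCIPP 25 µM replicate 3 (adjusted p 0.0524 to 0.170). The groups did not overlap in 2544 genes (20.2%, chance 10%).

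Genes that are often read in liver cells exposed to chemicals did not pass the unblocked test in any of the 7 comparisons. The drug-metabolizing CYP3A4 and CYP2B6 and the bile acid enzyme CYP7A1 lay at 0.399 to 0.804, 0 to 0.119 and 0.686 to 0.966 CPM over the groups, too low to be tested, and CYP1A1 at 3.66 to 6.80 CPM. The smallest adjusted p of the tested ones was that of HMOX1 at 2.5 µM TCIPP (log2 fold change 0.54 ± 0.116, 0.0571). DDIT3, a stress transcription factor, was at 16.3 ± 0.423 against 11.96 ± 2.21 CPM with TCIPP at 25 µM and DMSO (0.43 ± 0.152, 0.598). CPT1A, which carries fatty acids into mitochondria, had 0.49 ± 0.156 at 25 µM TCEP (0.170) and 0.55 ± 0.157 at 2.5 µM TCIPP (0.124). ALB was at 21800 ± 3560 CPM with DMSO and 16010 ± 2130 at 2.5 µM TCIPP (-0.445 ± 0.138, 0.149). For the DNA damage gene CDKN1A the fold changes against DMSO were -0.16, -0.17, -0.19 and -0.02 for TCEP at 250 and 25 µM and TCIPP at 25 and 2.5 µM (0.958, 0.284, 0.671 and 0.947). Among MKI67, a proliferation marker, MT1X, a metallothionein, ATF3 and the cholesterol synthesis gene HMGCS1, the smallest adjusted p against DMSO was 0.393, for HMGCS1 at 2.5 µM TCIPP (-0.15). With the block, HMOX1 fell from the lower to the higher concentration of each compound (adjusted p = 0.0315 and 0.00129).

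A total of 14 lists did not pass camera in any of the 7 comparisons without the block, nor with it in the 3 comparisons between treated groups. Blocked fits against DMSO were not part of this check, and the values below are those without the block. Their smallest adjusted p were 0.104 for AhR targets, 0.118 for phase III transporters, 0.130 for bile acid and FXR genes, 0.139 for PXR and CAR targets, 0.157 for p53 targets, 0.174 for leukocyte markers, 0.182 for both estrogen and androgen and interferon genes, 0.220 for metallothioneins, 0.303 for NF-kB targets, 0.355 for thyroid hormone genes, 0.365 for cholangiocyte markers, 0.370 for hepatocyte identity genes and 0.385 for phase I cytochrome P450 genes. Endothelial markers, with 4 tested members, summed to 4.34 to 6.51 CPM over the groups. Fibroblast and stellate markers summed to 57.9 to 65.0 CPM and hepatocyte identity genes to 49890 to 53900 CPM. Cholangiocyte markers summed to 2211 ± 227 CPM with DMSO (SD, n = 3) and to 1656 to 1779 CPM in the treated groups, and leukocyte markers to 5004 ± 709 and 4250 to 4693 CPM, sums that were not tested. The leukocyte list rests on 5 tested members of 20 listed, so its sum is no measure of leukocytes in the cultures.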

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

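In this part, the test of the low DMSO level, the 6 against 6 splits by compound, the guard that keeps a weak intron test from deciding, and the rule by which the depth test of the second pattern was to decide were chosen only after the results were seen. Signals outside the exon reads of the main test came from genes listed with no exon length and from intron reads. Of 296 tested genes with no exon length, RP1-140K8.5 fell in gene reads with the replicate block, with log2 fold changes of -0.632 from 25 to 250 µM TCEP and -0.779 from 2.5 to 25 µM TCIPP (edgeR adjusted p = 0.00968 and 0.00117). It was also lower with TCIPP than with TCEP at 25 µM (-0.792, adjusted p = 0.000954), where AC005077.14 was higher (0.753, adjusted p = 0.0366). Among intron reads, RP11-361L15.4 was higher at 25 µM TCEP than with DMSO without the block (1.734 ± 0.275 SE, adjusted p = 0.0419). With the block, intron reads of 5 of 10256 genes differed between the TCEP concentrations (2 up and 3 down), of 46 between the TCIPP concentrations (17 up and 29 down) and of 120 between the compounds at 25 µM (48 up and 72 down). NR1H4, the bile acid receptor, was higher in intron reads in all of these comparisons (0.625, 0.94 and 0.87), as it was in exon reads. Without the block the intron counts were 0 in those comparisons (491, 891 and 1156 at an unadjusted p under 0.05 with edgeR, the tool used). Single values were not screened for libraries that stand apart, since each group holds 3, but the counts against DMSO were highest without DMSO replicate 2 (1, 29, 5 and 307 for TCEP at 250 and 25 µM and TCIPP at 25 and 2.5 µM). In a test of the TCEP step against the TCIPP step 0 genes differed (208 at an unadjusted p under 0.05 with edgeR).

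The first pattern is the higher level of ATF4 genes in TCEP at 250 µM and TCIPP at 25 µM than in DMSO. A low level by chance in the DMSO libraries that both comparisons share is argued against by the lower-concentration libraries: in 18 of 18 pairs of a higher- and a lower-concentration library of the same compound, the list mean was above that of the lower concentration. Reads thinned to the shallowest library left 0.992 of the mean fold change, but thinning keeps expected CPM, so this value cannot decide on depth. Exon reads overlapped between DMSO (7.91 to 21.4 M), TCEP at 250 µM (6.63 to 21.0 M) and TCIPP at 25 µM (5.35 to 8.91 M). List means of DMSO (6.619 to 6.695) did not overlap those of the other groups (6.873 to 6.953 and 6.909 to 6.981), which argues against depth. GC content and gene length are argued against by random lists matched on them, among which the ATF4 list stood at percentile 100 of 10000. The hypothesis that remains is a biological one, that the higher concentrations of both compounds may raise the amino acid response, but plate layout and handling are not given in the sources used here and stay open.

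The second pattern is that fold changes from the lower to the higher concentration ran alike in TCEP and TCIPP. GC content and gene length are argued against, since removing their trends left a correlation of 0.427 across genes where it was 0.416 for the same genes before. With thinned reads the correlation was 0.361 (0.344 to 0.370 in 10 draws) against 0.450 for the same genes. It lay above 0.225, the bound set for depth as the whole cause. It was 0.804 of its unthinned value (0.764 less 2 SD of the draws), where 0.8 had been set as evidence against depth. But thinning keeps expected CPM, so a bias tied to depth would be kept as well. The value thus cannot decide on depth, which stays open. The intron share cannot be told apart, because the slope of each gene on it did not repeat between sets of libraries (correlation -0.00492), so the value of 0.0789 decides nothing, while the share was 8.75% at the higher and 8.17% at the lower concentrations. A biological explanation, a shared change with concentration, may hold but stays open beside depth, the intron share and anything else that cultures of the same level shared. Plate layout and handling are not given in the sources used here, so these cannot be told apart.

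The third pattern is the count of genes that followed concentration and compound over the 12 treated libraries with the block. Setting the 6 higher-concentration libraries against the 6 lower ones called 1118 genes (508 up, 610 down). Of 100 splits within replicate number, from 108 possible, 1 reached this count, the real one, and the highest other was 36. A random split is thus argued against, to the 1 in 100 that this test can reach. In the other splits the concentration difference adds to the spread and lowers their counts, so 36 is no measure of the contrast. The split cannot separate exposure from anything else that cultures of the same level shared. The split by compound called 36 genes (27 higher and 9 lower with TCIPP), reached by 2 of 100 splits, itself and the concentration split, but it was looked at because it stood highest among the other splits, so this does not test chance anew. For single comparisons the splits are too few for a share under 0.05. Of 10 splits of the 6 libraries, those with as many genes were 10, 10, 1 and 1 against DMSO (TCEP at 250 and 25 µM, TCIPP at 25 and 2.5 µM; real counts 0, 0, 1 and 12, highest other 0 each), 10 and 10 for the concentrations of TCEP and TCIPP (real 0 and 0, highest other 0 and 1) and 1 for the compounds at 25 µM (real 5, highest other 0). With the block, 1 of 4 splits in each treated comparison gave as many (real 185, 484 and 1100, highest other 1, 0 and 0).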

How the results depend on the processing

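The alternatives chosen after the data were seen were the fit of the 12 treated libraries, the blocked fits by other tools, with another scaling, filter or read column or with a library left out, every alternative for the correlation between the concentration steps (filter, scaling, block and each library left out), total gene reads, thinned reads, the deposited quantile-normalized values, and the relative log expression scaling for lists. Over the 679 values of named genes, 81 list calls, 10 counts and 2 correlations, 0 results past the threshold reversed under any alternative run. The 18 called gene results kept their call in 187 of 303 alternatives, lost it in 116 and reversed in 0. YARS lost it in 6 of 17. Of the 81 list calls, 78 were lost with an estimated correlation, 50 with fry, 11 of 80 with thinned reads, 4 with the block and 1 with the relative log expression scaling (liver cancer and progenitor genes between the TCIPP concentrations, 0.0511), and 38 were lost without 1 library. By fry, 1, 3, 2 and 4 of the 40 lists passed against DMSO (TCEP at 250 and 25 µM, TCIPP at 25 and 2.5 µM). Between treated groups 1, 13 and 13 did so for the TCEP step, the TCIPP step and the compounds at 25 µM. For named genes the block moved 385 past the threshold and no filter 304, and the cause was not tested. Simulated 1.5-fold changes were recovered in 58% to 72% of cases over the unblocked comparisons, in runs that also held larger changes. Recovery may be lower where few genes change. Reads were thinned to the shallowest library, of 5.35 M exon reads, and the counts against DMSO of 0, 0, 1 and 12 were too low for this to show whether depth limits them. Depth does limit the lowest genes: CYP2B6, at 0 to 0.119 CPM, lay near or under the 0.112 to 0.560 CPM that 3 counts stand for. Quantile-normalized values gave no result for TCIPP, and 9 libraries entered for TCEP.

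Counts of changed genes against DMSO moved as follows, in the order TCEP at 250 µM, TCEP at 25 µM, TCIPP at 25 µM and TCIPP at 2.5 µM, where the main counts were 0, 0, 1 and 12. DESeq2 gave 17, 155, 34 and 232, limma-voom 0, 4, 1 and 104, and no low-count filter 50, 618, 80 and 553. Library totals gave 0, 0, 0 and 35, unique reads 0, 2, 1 and 122, and a fit of only the groups compared (2 groups only) 0, 135, 0 and 23. Total gene reads gave 1, 0, 1 and 0, thinned reads 1, 3, 1 and 20, and an absolute log2 fold change of at least 1 left 0, 0, 0 and 2. The relative log expression scaling gave 0, 0, 1 and 11 and the 5 CPM filter 0, 0, 1 and 8. Leaving out 1 library in turn gave 0 to 1, 0 to 29, 0 to 5 and 0 to 307, the highest each time without DMSO replicate 2. The cause was not tested for any of these moves except the fold minimum, which removes genes by construction.

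For the treated comparisons, in the order TCEP at 250 against 25 µM, TCIPP at 25 against 2.5 µM and TCIPP against TCEP at 25 µM, the unblocked counts were 0, 0 and 5. DESeq2 gave 14, 72 and 334, no low-count filter 161, 345 and 756, thinned reads 0, 1 and 2, total gene reads 0, 0 and 13, library totals 0, 0 and 2, and 2 groups only 0, 0 and 0. A fold minimum of 1 left 0 in each, and leaving out 1 library gave 0 to 208 for the compounds at 25 µM. With the replicate block the counts were 185, 484 and 1100. Taking those as the starting point, no replicate block gave 0, 0 and 5 and the 12 treated libraries 555, 948 and 2096. Leaving out 1 library gave 18 to 111, 135 to 317 and 293 to 863. Blocked alternatives gave 187, 490 and 1107 with the relative log expression scaling, 204, 509 and 1196 with the 5 CPM filter and 231, 493 and 1214 with unique reads. The cause was not tested.

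Against DMSO, same-numbered libraries correlated at only 0.0164 to 0.158 in their deviations from the group means, not all over 0.1, so the numbers were not taken to pair them. With the block the counts there were 34, 1037, 47 and 941 in the order above. The blocked calls of TCEP at 25 µM and TCIPP at 2.5 µM shared 353 genes up and 239 down, where independent lists gave 25 and 14.3, and the shared DMSO libraries add to this by an amount not separated here. The ATF4 list with an estimated correlation was lost with the block at 250 µM TCEP (adjusted p = 0.0634 with an estimated correlation) and passed at 25 µM TCIPP (0.0460). Intron reads with the block gave 0, 147, 1 and 118 genes against DMSO, and RP1-140K8.5 was higher at 25 µM TCEP (0.67, adjusted p = 0.00501) and 2.5 µM TCIPP (0.66, 0.00632). As a hint from the data and not from the design, 15 of 15 libraries correlated best with a library of their own number when all other groups were searched. Within the single comparisons against DMSO, 5, 4, 2 and 6 of 6 libraries did so, in the order above. Of the 81 list calls the block ended those of liver cancer and progenitor genes (adjusted p 0.0578) and immediate early genes (0.0578) at 250 µM TCEP, heat shock genes at 25 µM TCEP (0.0877) and liver cancer and progenitor genes between the TCIPP concentrations (0.0598), and no other.

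The correlation between the fold changes of TCEP at 250 µM and TCIPP at 25 µM ran from 0.375 without TCIPP 25 µM replicate 2 to 0.625 without DMSO replicate 2.

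The values that changed sign all belong to genes that missed the threshold both ways, and the cause was not tested. With unique reads these included DDIT3 at 25 µM TCEP (0.069), MT1X at 2.5 µM TCIPP (-0.028), HMGCS1 between the TCEP concentrations (-0.021) and LYZ between the compounds (-0.076). Thinned reads turned HMOX1 at 250 µM TCEP (-0.029), MT1X at 2.5 µM TCIPP (-0.06) and MKI67 between the compounds (0.023). The quantile-normalized values turned MT-CO2 (0.041) and ALB (0) at 250 µM TCEP and DDIT3 at 25 µM TCEP (0.034). Total gene reads turned HIST1H2BN between the TCIPP concentrations (0.01), and the replicate block turned CYP1A1 at 25 µM TCIPP (0).

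Leaving out 1 library moved log2 fold changes across 0 as follows. At 250 µM TCEP against DMSO the ranges were -0.578 to 0.05 for CYP1A1, -0.053 to 0.118 for HMOX1, -0.132 to 0.001 for NQO1, -0.132 to 0.049 for ATF3 and -0.005 to 0.195 for CPT1A. At 25 µM TCEP they were -0.226 to 0.028 for ATF3, -0.138 to 0.094 for DDIT3 and -0.472 to 0.066 for MT1X. At 25 µM TCIPP they were -0.055 to 0.444 for PDGFRB, -0.344 to 0.295 for CYP1A1, -0.096 to 0.01 for HMOX1 and -0.2 to 0.063 for MKI67. At 2.5 µM TCIPP they were -0.063 to 0.028 for CDKN1A, -0.043 to 0.139 for ATF3, -0.16 to 0.072 for DDIT3 and -0.117 to 0.216 for MT1X. Between the TCEP concentrations they were -0.023 to 0.044 for CDKN1A, -0.073 to 0.181 for ATF3, -0.058 to 0.051 for HMGCS1 and -0.428 to 0.109 for MT1X. Between the TCIPP concentrations they were -0.021 to 0.07 for HMGCS1 and -0.002 to 0.257 for MKI67. Between the compounds at 25 µM they were -0.347 to 0.002 for MT2A, -0.034 to 0.278 for CD14, -0.004 to 0.077 for LYZ, -0.061 to 0.045 for CDKN1A, -0.092 to 0.003 for HMGCS1, -0.494 to 0.044 for MT1X, -0.146 to 0.117 for MKI67 and -0.051 to 0.182 for ALB.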

Other observations

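In this part the genes are named after their values were seen, and the split by compound was tested only after the result was seen. Setting the 6 higher-concentration against the 6 lower-concentration libraries, with the replicate block, gave 1118 changed genes of 12149 tested (508 up, 610 down). Among the genes higher at the higher concentrations were NR1H4, the bile acid receptor (log2 difference 0.67 ± 0.054 SE, edgeR adjusted p = 1.39e-06), the aldo-keto reductases AKR1C1 (0.66 ± 0.0592, adjusted p = 4.85e-06), AKR1C2 (0.57) and AKR1B10 (0.49), the amino acid transporter SLC6A14 (0.95), PSAT1 of serine synthesis (0.37), EIF4EBP1, which restrains translation (0.34), and the developmental transcription factor HOXD1 (1.10). Among the lower ones were IGFBP3 (-1.14 ± 0.0613, adjusted p = 1.22e-08) and IGFBP2 (-0.56), which bind insulin-like growth factors, the glucose transporter SLC2A3 (-0.505), EGLN3 (-0.62), ERO1L (-0.42), PAM, which amidates peptides (-0.48), ISM2 (-0.70), LOXL3 (-1.16) and the YAP target CYR61 (-0.70).

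Setting the 6 TCIPP libraries against the 6 TCEP libraries gave 36 genes, 27 higher and 9 lower with TCIPP. Among the higher ones were the immediate early genes JUN (0.26), FOS (0.61 ± 0.0974) and NR4A1 (0.46), the histone methyltransferases DOT1L (0.30) and KMT2C (0.25), the coactivator CREBBP (0.25) and EPAS1, the hypoxia factor HIF2A (0.24). Among the lower ones were the mitochondrial chaperonin HSPE1 (-0.27), SUV39H2 (-0.41), LSM3 (-0.36) and AIMP1, a scaffold of tRNA synthetases (-0.27). The genes named here had adjusted p of 0.0353 to 0.0457. Each compound's libraries hold a lower and a higher concentration, 25 and 250 µM for TCEP and 2.5 and 25 µM for TCIPP, so the groups differ in concentration as well as in compound. Between compounds at the level each series label calls high, TCIPP at 25 µM and TCEP at 250 µM, edgeR called 0 genes (656 at an unadjusted p under 0.05, smallest adjusted p 0.805; 1167 and 0.128 with the block). At the level called low, TCIPP at 2.5 µM and TCEP at 25 µM, it called 0 as well (718, 0.824; 1352 and 0.346 with the block). The comparison at the shared concentration of 25 µM also sets a treatment called high against one called low.

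Levels with DMSO were set beside those of this split for a few genes. For IGFBP3 and EGLN3 the higher concentrations lay nearer to DMSO than the lower ones did. IGFBP3 averaged 45.0 ± 19.3 CPM with DMSO (SD, n = 3), 120.9 ± 47.3 and 121.5 ± 48.4 CPM with TCEP at 25 µM and TCIPP at 2.5 µM, and 57.1 ± 22.7 and 53.9 ± 28.5 CPM with TCEP at 250 µM and TCIPP at 25 µM. EGLN3 averaged 49.1 ± 4.78 CPM with DMSO, 67.5 ± 9.91 and 75.0 ± 14.3 CPM at the lower and 46.1 ± 7.31 and 46.0 ± 7.79 CPM at the higher concentrations. For AKR1C1 both higher concentrations lay between DMSO and the lower concentration of their compound. It averaged 2134 ± 426 CPM with DMSO, 1047 ± 294 and 1093 ± 402 CPM at the lower and 1605 ± 530 and 1802 ± 712 CPM at the higher concentrations. The mitochondrial share of reads was 6.997% with DMSO, 6.15% and 6.04% at the lower and 6.60% and 7.03% at the higher concentrations. ATF4 genes ran otherwise, with DMSO and the lower concentrations near each other.

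The split by concentration was reached by 1 of 100 splits, the real one, so the lower-concentration cultures of both compounds may differ from the higher ones as a set. Whether that reflects the exposures or something those cultures shared, such as cell density or handling, was not tested, since the sources used here give no plate layout. Depth and intron share stayed open for the likeness of the steps, the intron test with a value of 0.0789.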
